A study of Mus musculus with 6 samples.

How the data were processed

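Gene expression was measured in mouse embryonic stem cells on 6 Affymetrix Mouse Genome 430 2.0 arrays, 3 of wild-type cells and 3 of cells whose Dido3 protein lacks its C-terminal part. The labels call the 3 arrays of each group biological replicates. The sample titles do not say how many independent cell lines each group holds. If it holds 1, the p-values measure the spread between cultures of that line and not between lines. Per the labels' protocols, the cells were grown in stem cell medium with leukemia inhibitory factor (LIF), which keeps mouse embryonic stem cells self-renewing. Total RNA was extracted with TRIzol, cleaned on RNeasy columns, checked for degradation and labelled with biotin in 1 cycle of amplification, per the labels' protocols. The deposited values were log2 expression values per probe set, made by the authors from the scanned arrays. The method of summarising and normalising them is not given in the sources used here; the log2 scale was read from the values themselves. Array medians lay between 4.80 and 4.86 and the brightest probe set of each array between 13.7 and 13.8, so the values were used without further scaling. The number of arrays limits the precision of every difference given.

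The table held 45101 probe sets, of which 64 were control probe sets that were left out of the tests, and the other 45037 were tested. In the platform annotation, 34958 probe sets had 1 gene symbol, 13 control probe sets included, and 932 had several. Neither the 13 controls nor the 932 were used for a gene. A further 9160 probe sets other than controls were unnamed here. Symbols were checked through Entrez identifiers against the RefSeq gene table of the mouse assembly GRCm38.p6, where 34754 probe sets matched and 0 symbols had to be changed. No genome build is tied to the arrays, so no coordinates are given, and the chromosome of a gene was used only to group genes. Genes were not named from a probe set with several symbols. At the gene level, each of 18193 genes was represented by its probe set with the highest mean over all 6 arrays. A gene was called expressed when its mean exceeded 4.82, the median log2 value of all probe sets.

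Truncated cells were compared with wild-type cells with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets or all genes. The threshold was an adjusted p of 0.05. All tests were two-sided. A difference is the truncated mean minus the wild-type mean on the log2 scale, with its standard error (SE) from limma; group values are means ± SD. Of 30 gene lists fixed before the data were examined, 28 were tested with camera of limma at a preset correlation of 0.01 and adjusted together; sex-linked marker genes and the neighbours of the targeted gene were described by value. Of 571 genes on the lists, 529 were measured. Expressed genes were also grouped by chromosome and tested with camera, adjusted over the 19 autosomes and X. Measures with 1 value per array were compared by an exact permutation test, whose smallest p with 3 against 3 arrays is 0.1.

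Genes named in the text were chosen by a rule fixed before the data were examined. It takes all probe sets of Dido1; the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, leaving out predicted and clone names; up to 4 members past the threshold of each list, by size; and 13 genes of pluripotency and of the germ layers that are always named. Of these, 1 had no probe set named here and was not analysed here. Genes named outside the rule are marked as chosen after their values were seen.

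Fixed alternatives were the replicate number as a block, quantile normalisation, median centring, leaving out dim probe sets or those whose names end in _x_at or _s_at, a trended and robust variance, array weights, leaving out each array, the mean of all probe sets of a gene, an estimated correlation in camera, and fry in place of camera. Added after seeing the data were a block for 2 arrays with high poly-A spike-in controls, the other 4 arrays alone, the mean of a fibroblast marker list as a covariate, and autosomal genes alone. The 2 arrays were set apart because the mean of their 24 poly-A control probe sets lay more than 2 log2 units above the median array. The fits were tested on simulated arrays for the 18193 genes with the spread of the real ones: 81 of 100 genes changed by 1 log2 unit and 99 of 100 changed by 2 were recovered, with 3 unchanged genes called. In simulated arrays with no change, 0 genes were called. The simulated genes were drawn independently, without the fibroblast and spike-in differences of the real arrays. These counts therefore do not show how the fits behave where arrays differ in that way. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.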

Results

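The data consist of 6 expression profiles of mouse embryonic stem cells kept in LIF, 3 from wild-type cells and 3 from cells with a C-terminally truncated Dido3, grown in parallel. Dido3 is the longest protein made from the gene Dido1 (death inducer-obliterator), and the series addresses how Dido acts on self-renewal and differentiation of these cells. Pearson correlations over all probe sets were 0.978 to 0.993 among wild-type arrays, 0.991 to 0.995 among truncated arrays and 0.973 to 0.984 between the groups. The brightness of 3' against 5' control probe sets, a sign of RNA quality, was higher in all 3 wild-type arrays, in a design too small to pass the threshold. For beta-actin the log2 difference was 1.07 ± 0.11 in wild-type and 0.85 ± 0.02 in truncated arrays (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). For Gapdh it was 0.309 ± 0.011 and 0.223 ± 0.023 (exact permutation p = 0.1).

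Arrays of both groups differed in fibroblast transcripts. The mean of 21 fibroblast markers, most of them collagens and other matrix genes, 19 of which were expressed above the limit and 0 of which stood on another list, was 5.23 on wild-type replicate 3 and 6.63 on truncated replicate 2, against 8.13 to 8.67 on the other 4 arrays. The same 2 arrays had high poly-A spike-in controls, with means of 12.1 and 12.5 against 6.12 to 7.85. Each group held 1 of these arrays, so differences are also given within the 4 other arrays and within this pair. The group means of the fibroblast list were 7.46 ± 1.93 in wild-type and 7.63 ± 0.87 in truncated arrays (SD, n = 3 each; exact permutation p = 1).

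**Figure D1:**
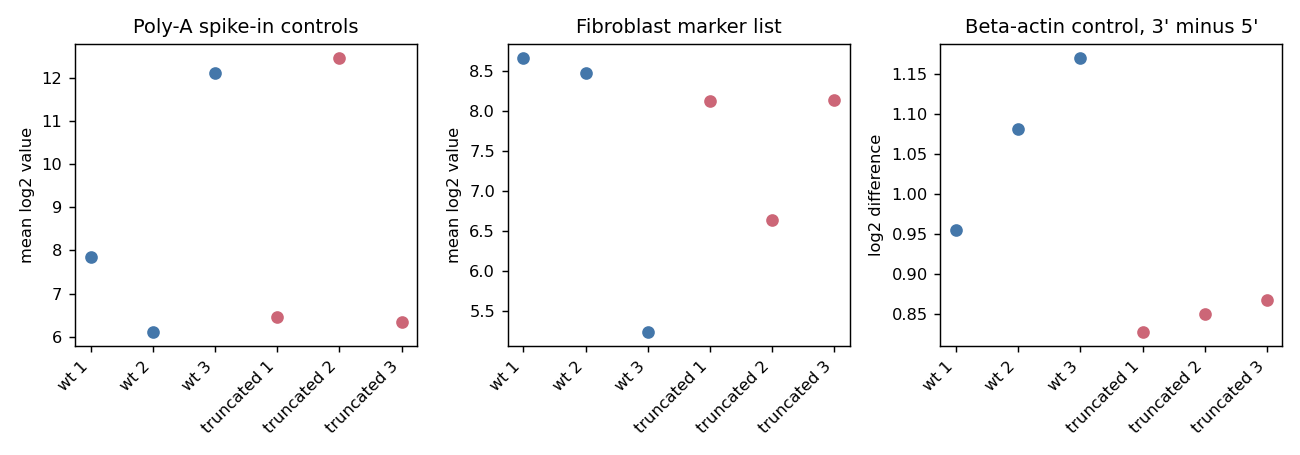
Quality measures of each array, 1 point per array, blue for wild type (wt) and red for truncated cells: the mean log2 value of the poly-A spike-in controls, the mean log2 value of the fibroblast marker list, and the 3' minus 5' log2 difference of the beta-actin control. Wild-type replicate 3 and truncated replicate 2 stand apart in the first 2 panels, with spike-in means of 12.1 and 12.5.

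The targeted gene was measured by 5 probe sets, and 2 of them were lower in the truncated cells. The probe set representing Dido1 (1456405_at) fell from 8.38 ± 0.19 to 6.88 ± 0.35 (SD, n = 3 each), a difference of −1.50 (SE 0.19), or 2.83-fold lower, with a limma adjusted p of 0.0104. A second probe set, 1437647_at, fell from 5.62 ± 0.10 to 4.15 ± 0.03 (adjusted p = 0.00106). The probe set 1437182_at was at 7.14 ± 0.26 and 7.82 ± 0.15, a difference of 0.68 that did not pass (adjusted p = 0.0721). It passed at 0.0427 with the spike-in batch as a block, and its adjusted p ranged from 0.0372 to 0.269 over the alternatives. The remaining 2, 1431258_at and 1444744_at, differed by 0.05 and 0.03 (adjusted p = 0.869 and 0.954). Where each probe set lies relative to the removed C-terminal part was not analysed here, and a probe set outside that part checks nothing. The difference of 1456405_at was −1.61 in the 4 arrays with low spike-in controls and −1.27 in the other pair. Leaving out wild-type replicate 2, truncated replicate 1 or truncated replicate 3 gave −1.48, −1.43 and −1.37 with adjusted p of 0.0599, 0.0754 and 0.0578, past the threshold in none of these 3 cases; over all alternatives the adjusted p ranged from 0.00298 to 0.0754. The mean of the 5 probe sets gave a smaller difference, −0.44 (adjusted p = 0.0374).

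**Figure D2:**
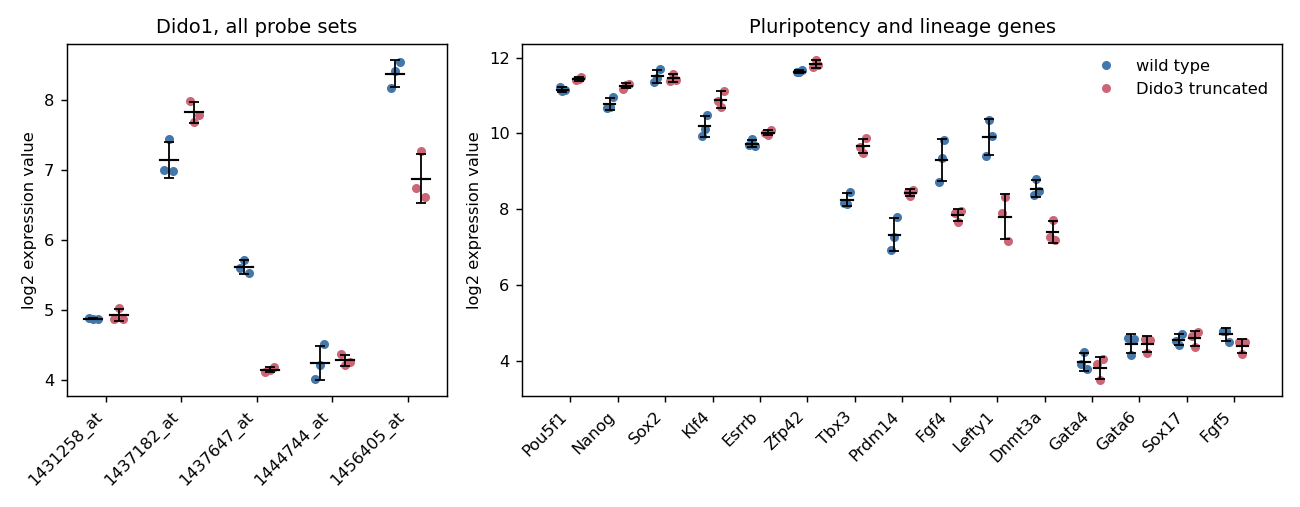
Log2 expression values of the 5 Dido1 probe sets (left) and of genes of pluripotency and early lineages (right) on each array, blue for wild type and red for truncated cells; horizontal lines are group means and bars 1 SD (n = 3). Probe sets 1456405_at and 1437647_at lie lower in all 3 truncated arrays, while Pou5f1, Sox2 and Zfp42 differ by 0.28, −0.06 and 0.20.

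The truncated cells differed from wild-type cells in 850 genes. Y-linked RNA also set the groups apart, as given below, so these genes and the lists below cannot be assigned to the truncation alone. Of the 18193 genes tested, 491 rose and 359 fell, and 300 changed at least 2-fold (193 up, 107 down). With autosomal genes tested alone, 319 rose and 306 fell, and at least 2-fold 142 rose and 98 fell. At the level of probe sets, 1261 of 45037 changed (756 up, 505 down). The median size of the gene changes was 0.85 log2 units, and 766 of the 850 genes were expressed above the median of the arrays. The groups did not overlap for 8381 probe sets, or 18.6%, against 10% by chance. Of 305 changed genes with another expressed probe set, the others all moved the same way in 235. In 99 of the 305, another expressed probe set also passed the threshold in the same direction. With the spike-in batch as a block, 1569 genes changed. In the 4 arrays with low spike-in controls alone 931 genes changed, and 860 of these (92.4%) had the same direction in the remaining pair. With the level of fibroblast markers as a covariate, 1928 genes changed. The count fell to 510, 241, 129, 502 and 173 genes without wild-type replicate 1, wild-type replicate 2 or truncated replicate 1, 2 or 3, where fewer arrays were tested, and was 1191 without wild-type replicate 3. The 2-fold count was 169, 112 and 137 without wild-type replicate 2, truncated replicate 1 and truncated replicate 3.

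With predicted and clone-named genes left out, a pair of PRAME-family genes led the rises, followed by X-linked genes, among them Tex13b and Rhox13, which are known from the testis. Pramel6 (1456270_s_at) rose from 4.34 ± 0.50 to 10.82 ± 0.02 (SD, n = 3 each), with an adjusted p of 0.000115. Pramel7 (1439810_s_at), a gene of the inner cell mass that responds to LIF, rose from 4.47 ± 0.42 to 9.54 ± 0.08 (adjusted p = 0.000191). Both genes were read by probe sets that can cross-hybridise, so the sizes of these rises may not be theirs alone. Both kept direction and call under every alternative run. Tex13b rose by 4.35, Egfl6 by 4.15, Nxf3 by 3.46, Pnma5 by 3.24, Rhox13 by 3.16 and Efhc2 by 2.91; these 6 genes are X-linked. The remaining 4 of the 12 largest rises were autosomal: Zfp672 (2.85), Rcsd1 (2.83), Akr1cl (2.60) and Nefm (2.59), a neurofilament subunit. Adjusted p for these 10 genes ranged from 4.76e-05 for Nxf3 to 0.00981 for Akr1cl. The wild-type means of 9 of the 12 genes, Pramel6 and Pramel7 included, lay below the expression limit, so the sizes and order of these rises are against background. For Rcsd1, 2 other expressed probe sets differed by −0.02 and −0.07 and did not pass. For Tex13b, the expressed probe set 1432159_a_at differed by 1.48 and did not pass (limma adjusted p = 0.186).

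Y-linked transcripts led the falls. Eif2s3y fell from 8.58 ± 0.14 to 3.68 ± 0.23 (SD, n = 3 each), and Uba1y from 6.63 ± 0.46 to 3.54 ± 0.39, with adjusted p of 4.76e-05 and 0.0039. Dsp, which encodes the desmosomal protein desmoplakin, fell by 2.55, and the keratin gene Krt8 fell by 1.90. The imprinted gene Phlda2 fell by 2.28. Lefty1, which encodes an antagonist of Nodal, fell by 2.10. Carm1, an arginine methyltransferase, fell by 2.05 and the methyltransferase gene Eef1akmt2 fell by 1.99. Carm1 was read only by a probe set that can cross-hybridise, so it was not tested with such probe sets left out. Sycp3, of the synaptonemal complex, fell by 1.86, and Prdm1, a repressor needed for germ cell formation, fell by 1.82. Ldhb, a subunit of lactate dehydrogenase, fell by 1.76 and Gna14, a G protein subunit, fell by 1.69. Adjusted p for these 10 genes ranged from 0.00371 for Carm1 to 0.0341 for Dsp. The truncated means of 5 of the 12 genes, those of Eif2s3y and Uba1y included, lay below the expression limit, so the sizes of these falls are against background. All 24 genes had the same direction in the 4 low spike-in arrays and in the other pair. That was fixed by choosing genes whose groups did not overlap, so it is no check on the spike-in batch.

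Of the 65 named genes that changed, 18 kept their call with each array left out in turn. These were Pramel6, Pramel7, Tex13b, Egfl6, Nxf3, Efhc2, Zfp672, Rcsd1, Nefm, Eif2s3y, Uba1y, Carm1, Eef1akmt2, Gna14, Tbx3, Apoe, Gata3 and Pmaip1. The replicate block cost 18 of the 65 genes their calls, the 4 low spike-in arrays alone 20 and the mean of all probe sets 11. Leaving out probe sets that can cross-hybridise cost Dsp (−1.91, adjusted p = 0.0594) and Pkp2 (−0.79, adjusted p = 0.0507) their calls, with the direction kept. Lss, Dlk1, Meg3 and Xist, described below, also lost theirs. With each array left out in turn, the other genes lost the call in at least 1 case; 19, 37 and 4 were lost without wild-type replicates 1, 2 and 3, and 47, 28 and 40 without truncated replicates 1, 2 and 3.

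Pou5f1, Nanog and Sox2 were high in both groups. Pou5f1, the gene for Oct4, was at 11.15 ± 0.06 in wild-type and 11.44 ± 0.04 in truncated cells (SD, n = 3 each; limma adjusted p = 0.125). Nanog was at 10.78 ± 0.15 and 11.25 ± 0.07 (adjusted p = 0.0583); it passed at 0.032 with the spike-in batch as a block, and its adjusted p ranged from 0.0177 to 0.202 over the alternatives. Sox2 differed by −0.06 (adjusted p = 0.877). Of the 18 measured members of the core pluripotency list, 2 rose, Foxd3 by 1.15 and Mybl2 by 0.75, and 1, Fgf4, fell by 1.46 (SE 0.27). Fgf4 encodes the growth factor through which these cells activate ERK. Its probe sets disagreed: 1420085_at fell by 1.52, 1450282_at differed by 0.01, and 1449729_at rose from 4.49 ± 0.55 to 10.43 ± 0.29 (adjusted p = 0.00055). Whether 1449729_at measures Fgf4 transcripts was not tested. The list as a whole did not shift (mean 0.02, adjusted p = 0.931).

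At the preset correlation of camera, genes of naive pluripotency were higher as a group and genes of the formative and primed epiblast lower, but neither list passed at an estimated correlation (adjusted p = 0.519 for both) or with fry (adjusted p = 0.0754 and 0.128). Of 21 naive genes measured, 4 rose and 0 fell. Tbx3 rose from 8.25 ± 0.17 to 9.67 ± 0.19, Jam2 by 1.35, Prdm14 by 1.11 and Nr0b1 by 0.56. Other probe sets of Jam2 also passed. Of these, 1419288_at, 1431416_a_at and 1436568_at rose by 1.47, 1.26 and 1.76, while 1431417_at fell by 2.14. Klf4 differed by 0.71 (adjusted p = 0.0764; 0.0194 to 0.244 over the alternatives), Esrrb by 0.29 (0.149) and Zfp42 by 0.20 (0.309); a second probe set of Klf4, 1417395_at, rose by 0.85 (adjusted p = 0.028). The mean difference of the naive list was 0.30 (adjusted p = 0.00178). Adjusted over the list alone, 6 rose and 2 fell. Of 17 formative and primed genes, 3 fell and 0 rose: Zic5 (−1.21), the DNA methyltransferase Dnmt3a (−1.15) and Tcf15 (−0.71). The list averaged −0.38 (adjusted p = 0.000758), and 3 fell when adjusted over the list alone. Other expressed probe sets of Dnmt3a differed by 0.33, 0.18, −0.62 and −0.96, and none of them passed. Fgf5, a marker of primed cells, differed by −0.30 (adjusted p = 0.306). The naive mean was 0.32 in the 4 low spike-in arrays and 0.27 in the other pair; the formative mean was −0.50 and −0.14. With the batch as a block both lists passed, at 0.00393 and 0.000645.

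The lists of germline genes and of 2-cell-like genes were higher in the truncated cells as groups at the preset correlation of camera, but neither passed at an estimated correlation (adjusted p = 0.519 for both). With fry the germline list did not pass (adjusted p = 0.0754), and most members of both lists did not pass the gene-level test. Of 24 genes of germline and meiosis, 9 rose, 1 fell and 14 did not pass, with a mean difference of 0.73 (adjusted p = 0.000137). The largest rises were those of Rhox13, Dazl, an RNA-binding protein of germ cells (2.33), Taf7l (2.28) and Piwil2, of the piRNA pathway (2.01); the member that fell was Sycp3. Adjusted over the list alone, 12 rose and 1 fell. The mean of the list was 0.94 in the 4 low spike-in arrays and 0.33 in the other pair, and the adjusted p was 0.000521 with the batch as a block. Of the 19 genes of the 2-cell-like list 7 were measured, none of them a Zscan4 gene, and 3 rose: Pramel6, Pramel7 and Tcstv1 (0.59), the last below the expression limit in both groups. The mean rested on Pramel6 and Pramel7, and the count was the same when adjusted over the list alone. The list had a mean of 1.69 and a median of 0.21 (adjusted p = 0.0012, and 0.00448 with the batch as a block). Over the alternatives its mean ranged from 0.829 to 2.745, and Pramel6 and Pramel7 were both read by probe sets that can cross-hybridise. The mean was 1.82 in the 4 low spike-in arrays and 1.43 in the other pair.

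The lists of epithelial junctions and of cholesterol synthesis were lower as groups at the preset correlation of camera, but neither passed at an estimated correlation (adjusted p = 0.519 for both) or with fry (adjusted p = 0.141 and 0.173). Most of their members did not pass. Of 15 junction genes, 3 fell and 0 rose: Dsp, the splicing regulator Esrp1 (−1.17) and the desmosomal plakophilin Pkp2 (−1.14), and 6 fell when adjusted over the list alone. The expressed probe sets 1429183_at and 1460511_at of Pkp2 differed by −0.79 and −0.26 and did not pass. The mean of the list was −0.61 (adjusted p = 0.000137). It was −0.58 in the 4 low spike-in arrays and −0.67 in the other pair, and the adjusted p was 3.34e-05 with the batch as a block. Of 16 cholesterol genes, 3 enzymes fell, Idi1 (−0.95), Lss (−0.58) and Fdps (−0.47), and 0 rose. None of the 3 passed in the mean of all probe sets (adjusted p 0.0635 to 0.249), where Idi1 (−1.06) and Lss (−0.63) differed as much as before and Fdps less (−0.20), and Lss did not pass without probe sets that can cross-hybridise (−0.14, adjusted p = 0.618). The list averaged −0.41 (adjusted p = 0.000608), with −0.25 in the 4 low spike-in arrays, −0.74 in the other pair and an adjusted p of 0.000374 with the batch as a block. Adjusted over the list alone, 9 fell and 2 rose.

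Targets of p53 were higher as a group at the preset correlation of camera, but did not pass at an estimated correlation (adjusted p = 0.519) or with fry (adjusted p = 0.0988). Of 19 measured, 2 rose and 0 fell: Pmaip1, a pro-apoptotic member of the BCL2 family, by 2.04 and the antiproliferative gene Btg2 by 0.97. The mean was 0.42 (adjusted p = 0.000758), and 7 rose when adjusted over the list alone. It was 0.48 in the 4 low spike-in arrays and 0.31 in the other pair, and the adjusted p with the batch as a block was 0.000774. The 7 lists that passed kept their calls under each alternative that used a preset correlation, with an adjusted p of at most 0.0225, that of the 2-cell-like list; none passed with an estimated correlation, and fry called only the 2-cell-like list (adjusted p = 0.00761).

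**Figure D3:**
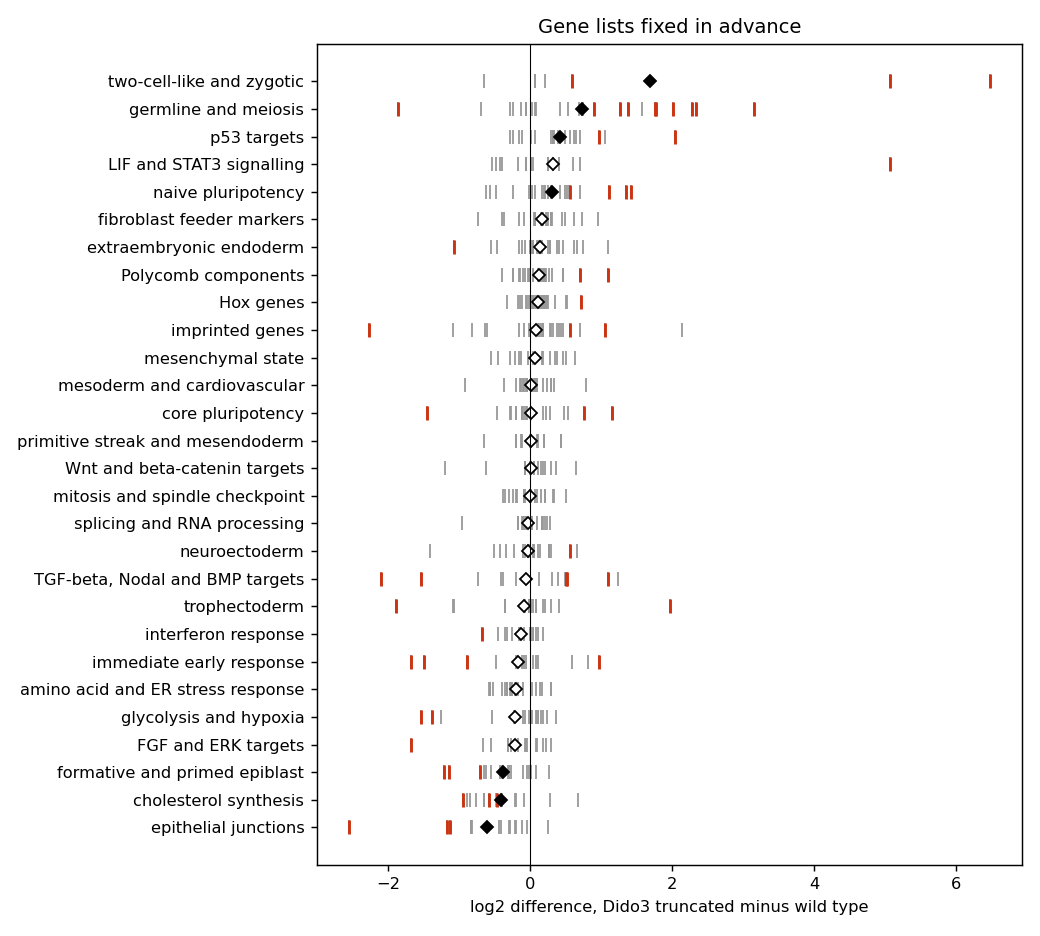
Log2 difference, truncated minus wild type, of the members of the 28 tested lists; each tick is a gene, red ticks are genes past the threshold, and diamonds are list means, filled where camera passed at its preset correlation. Filled diamonds lie at 1.69 for the 2-cell-like list and at −0.61 for epithelial junctions.

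The other 21 lists did not pass (adjusted p 0.134 to 0.986), although single members changed. Among immediate early genes, Egr1 (−1.68), which is also a target of ERK, Fos (−1.49) and the mRNA decay factor Zfp36 (−0.89) fell, and Btg2 rose. Of the targets of TGF-beta, Nodal and BMP, Lefty1 and Lefty2 (−1.54) fell, while Smad6 rose by 1.09 and Tgif1 by 0.52. The Polycomb genes Bmi1 and Cbx2 rose by 1.10 and 0.70. In the trophectoderm list Gata3 rose from 3.94 ± 0.29 to 5.92 ± 0.22 and Krt8 fell, while Cdx2 differed by 0.21 (adjusted p = 0.541). In the endoderm list Apoe fell by 1.08, and Gata4, Gata6 and Sox17 differed by −0.16, −0.01 and 0.04 at values near the floor of the arrays. Pdk1 and Ankrd37, from the list of glycolysis and hypoxia, fell by 1.54 and 1.38. Another expressed probe set of Pdk1, 1435836_at, differed by −0.22 (limma adjusted p = 0.502). The imprinted genes Dlk1 and Meg3 rose by 1.05 and 0.57, but differed by 0.18 and 0.17 without probe sets that can cross-hybridise (adjusted p = 0.648 and 0.678). Smaller changes were those of Irf1 in the interferon list (−0.68), Hoxc10 among Hox genes (0.72) and Lhx2 in the neuroectoderm list (0.56), the last 2 below the expression limit; Pax6 differed by −0.23 (adjusted p = 0.29). In the LIF and STAT3 list, Pramel7 was the only gene of 17 past the threshold. No member changed among the lists of mitosis and spindle checkpoint (23 genes), splicing (21), mesoderm (24), primitive streak (15), Wnt targets (14), amino acid and ER stress (20), fibroblast markers (21) and mesenchymal state (16).

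Some lists passed only in part of the arrays. The fibroblast list averaged −0.44 in the 4 low spike-in arrays (adjusted p = 0.000363) and 1.40 in the other pair, and the mesenchymal list −0.33 (adjusted p = 0.00821) and 0.86. Targets of FGF and ERK averaged −0.38 in the 4 arrays (adjusted p = 0.0032) and 0.11 in the pair, and interferon genes −0.25 (adjusted p = 0.0165) and 0.12. All 4 lists thus had opposite directions in these 2 sets of arrays. The list of amino acid and ER stress passed with the spike-in batch as a block (mean −0.20, adjusted p = 0.039). Without wild-type replicate 3, 13 lists passed in place of 7. The mean, the median and the direction of the camera test differed in sign for 6 lists that did not pass: core pluripotency, neuroectoderm, trophectoderm, the targets of TGF-beta, Nodal and BMP, glycolysis and hypoxia, and mesenchymal state.

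X-linked genes were higher in the truncated cells as a class, and 3 of 9 measured Y-linked genes were lower, at or near the floor, while the other 6 did not pass. Of these 6, all but Sry had wild-type means below the expression limit, from 3.29 to 4.76, where a fall could hardly be measured. Of 374 expressed X-linked genes, 85.8% were higher in the truncated cells, with a median difference of 0.47 (quartiles 0.19 and 0.77), 114 rose and 3 fell. Camera gave an adjusted p of 2.01e-29, and 0.0422 with an estimated correlation. The medians of the 19 autosomes lay between −0.08 and 0.01, and none of them passed. The X-linked median was 0.50 in the 4 low spike-in arrays and 0.40 in the other pair. X-linked genes made up 26.6% of the 429 expressed genes that rose, against 3.2% of all expressed genes (odds ratio 15.3, 95% interval 11.8 to 19.7; Fisher's exact test, p = 6.95e-76; genes are not independent). Of the sex-linked markers, Eif2s3y fell as given above and Uty fell from 5.96 ± 0.10 to 4.67 ± 0.34 (SD, n = 3 each; adjusted p = 0.0123). Kdm5d lay near the floor in both groups, at 3.29 and 3.20, and Sry, added after its values were seen and measured by a probe set that can cross-hybridise, was at 5.81 in both. Xist, the RNA that silences an X chromosome, was at 8.74 ± 0.20 and 9.31 ± 0.04 (adjusted p = 0.0483), but its direction was reversed without probe sets that can cross-hybridise (−0.69, adjusted p = 0.609), where the probe set left was below the expression limit at 4.49 and 3.80, and in the mean of its probe sets (−0.03).

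**Figure D4:**
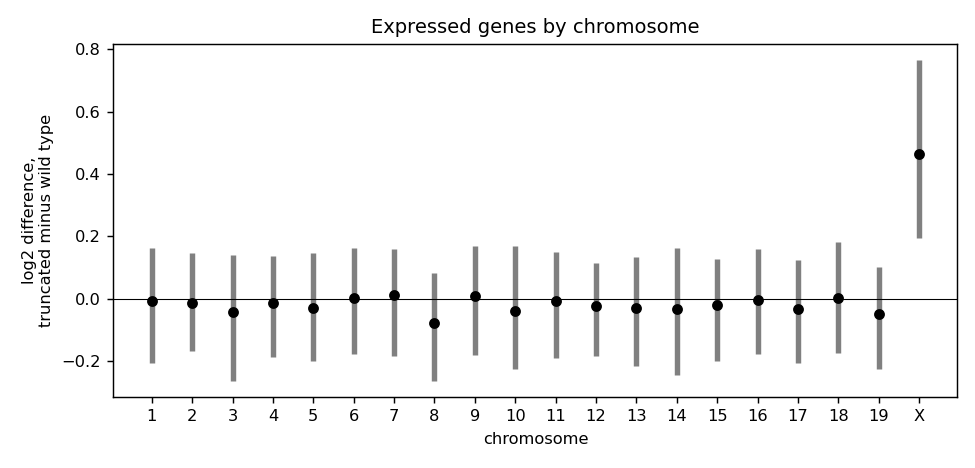
Median log2 difference, truncated minus wild type, of the expressed genes of each chromosome (points), with bars from the lower to the upper quartile of genes. The X chromosome has a median of 0.47, while the medians of the autosomes lie between −0.08 and 0.01.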

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

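The 3 tests in this part were chosen after the spike-in levels had been seen.

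Poly-A control transcripts, bacterial sequences added to the RNA before labelling and used in no comparison, were far brighter on 2 arrays, where they lay 4.245 log2 units above the median wild-type array on wild-type replicate 3 and 4.607 on truncated replicate 2. Degraded RNA stays open, because the beta-actin 3' minus 5' difference was 1.17 on wild-type replicate 3, the highest of all 6 arrays, but 0.85 on truncated replicate 2, within the range of the other 4 and −0.23 from their highest, while the Gapdh differences of both (0.297 and 0.238) lay within that range for Gapdh, 0.197 to 0.317. A processing difference that the 2 arrays share also stays open, because the correlation of their deviations from group means (r = 0.389 over expressed probe sets) was near that of wild-type replicate 2 with truncated replicate 1 (0.364), and centring links such values. The fibroblast list of both arrays lay below that of the other 4, by −1.50 at the closest, and Col1a2, its brightest gene and chosen after its values were seen, was at 6.59 and 8.66 against 10.43 to 11.25. A separate culture or preparation with less fibroblast RNA is a candidate explanation, while no biological explanation was tested, since each group holds 1 of these arrays.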

How the results depend on the processing

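The spike-in block, the 4 low spike-in arrays, the fibroblast covariate and the autosomal genes were added after seeing the data. With 3 arrays per group, leaving 1 out lowered the count of genes, except for wild-type replicate 3, without which 1191 genes changed. Signal close to the floor limits dim genes such as Gata4 and Sox17.

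The main fit was fixed in advance without a replicate block, because no label ties a replicate number of the truncated cells to a wild-type culture. Same-numbered arrays deviated together for number 1 alone (r = 0.329, against −0.368 and −0.12 for 2 and 3). Truncated 1 correlated more with wild-type 2 (0.364). With the replicate block, 731 probe sets and 466 genes changed, 420 of them among the 850, and 7 lists passed; array 1 of the wild type correlated best with truncated 1 (0.329), but wild-type 2 and 3 did not correlate best with their own numbers. The cause was not tested, apart from the degrees of freedom the block takes.

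Probe sets changed numbered 2495 with array weights, 2366 with the spike-in block and 3084 with the fibroblast covariate; 8381 had groups that did not overlap. Genes changed numbered 1573, 1569 and 1928 under the first 3 of these. The cause was not tested. Leaving out 1 array gave 149 to 1669 probe sets, 129 to 1191 genes, 112 to 391 genes at least 2-fold changed, 7 to 13 lists and a Dido1 difference of −1.37 to −1.70; fewer arrays were tested. The mean of all probe sets gave Dido1 −0.44, since 3 of its 5 probe sets did not fall. In the 4 low spike-in arrays 11 lists passed, with an estimated correlation 0 and with fry 1. The X chromosome alone passed under every alternative run for chromosomes. The other settings kept each count within 1.5 times.

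Some values near 0, and 2 called genes, reversed. For Fgf4 the mean of all probe sets takes in 1449729_at, which rose by 5.94 while 1420085_at and 1420086_x_at fell. The causes of the other reversals were not tested. The mean of all probe sets gave Fgf4 0.74, Xist −0.031 and Pax6 0.038, and leaving out cross-hybridising probe sets gave Xist −0.69. Gata6 was 0.13 with array weights and 0.18 in the 4 low spike-in arrays, where Dido1 1431258_at was −0.0027. Leaving out 1 array gave −0.0018 to 0.075 for 1431258_at, −0.080 to 0.16 for 1444744_at, −0.13 to 0.040 for Sox2, −0.27 to 0.0032 for Gata4, −0.15 to 0.11 for Gata6 and −0.048 to 0.15 for Sox17. Of 1325 alternative values of the 74 single results past the threshold, 1067 kept direction and call, 255 lost the call and 3 reversed.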

Other observations

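The tests of sex chromosomes and of a few induced X-linked genes were chosen after the result was seen. So were those of X-linked members of the germline list and of the number of active X chromosomes, and the genes in the next paragraph. Predictions for the spike-in batch and for other divisions of the arrays were written before. The spike-in settings themselves were added after seeing the data.

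Of 9 further regulators and X-linked genes looked at, 1 passed. Dusp9, an X-linked phosphatase that restrains ERK, rose from 7.47 ± 0.56 to 8.97 ± 0.07 (SD, n = 3 each; limma adjusted p = 0.028). Among widely expressed X-linked genes, Kdm6a differed by 0.73, Atrx by 0.53, Hprt by 0.44, Kdm5c by 0.44 and Pgk1 by 0.37, and none of these 5 passed. With the spike-in batch as a block Kdm6a passed (limma adjusted p = 0.0186, against 0.0594 without it) and the others did not. Dnmt3b differed by −0.40 (adjusted p = 0.29), Uhrf1 by −0.33 (0.175) and Dnmt3l by −0.02 (0.98). The 10 measured neighbours of Dido1 averaged 0.09 and none passed; the widest difference was that of Tcfl5, at 0.89 (adjusted p = 0.0858).

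The median of X-linked genes was higher and Eif2s3y, Uba1y and Uty were lower in all 3 truncated arrays. A few strongly induced X-linked genes would not place 85.8% of them higher. The spike-in batch is argued against by X-linked medians of at least 0.404 within both sets of arrays. Eif2s3y was at 8.43 to 8.69 in the wild-type arrays and at 3.43 to 3.86, below the expression limit, in the truncated arrays. The groups thus did differ in this Y-linked RNA. Whether truncated cells had 2 active X chromosomes against 1 X and a Y in wild-type cells stays open. The median of all expressed X-linked genes, 0.47, lay between no change and the 1 log2 unit of doubled dosage. How large a difference doubled dosage gives on these arrays was not tested. That the 2 groups of cells differ in sex chromosomes is a hypothesis formed on these data. Under it, genotype and sex chromosomes differ between the same arrays. A broad action of the truncation on X-linked genes was not tested.

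The germline list was higher in the truncated cells at the preset correlation of camera, but did not pass at an estimated correlation (adjusted p = 0.519) or with fry (adjusted p = 0.0754). X-linked members are not its whole source, because 7 autosomal members rose and 1 fell, and the 22 autosomal members passed camera at the preset correlation with a mean of 0.55 (0.000128 before adjustment, adjusted p = 0.000872). The spike-in batch is argued against by the 4 arrays with low controls, where 10 members rose, 0 fell and the list passed camera at the preset correlation (9.63e-07 before adjustment, adjusted p = 2.7e-05), and by a mean of 0.33 in the other pair. Whether the truncation or the number of active X chromosomes accounts for it cannot be told apart here, because 0 arrays of truncated cells had Eif2s3y above the expression limit. The same applies to the other lists and autosomal genes that differed, among them the naive and formative genes, which may respond to X dosage. A truncated line with a Y chromosome would be needed.

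The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 1261 probe sets, 850 genes and 300 genes changed at least 2-fold, the highest of the 9 others 0 in each case, so 1 of 10 was as large for each. For gene lists the real division gave 7 and the highest other 11, and 6 of 10 were as large. Of the divisions that placed both arrays with high spike-in controls on 1 side, 2 gave 8 lists and the others 5 and 4; with that batch as a block, 8 lists passed. For chromosomes, 10 of 10 divisions gave at least 1, with 2 the highest other, and X was called in each. The X-linked median was 0.47 in size in the real division and 0.13 to 0.20 in the others. Each other division placed arrays of both groups on each side in unequal numbers, so it kept part of the group difference. That difference also added to the spread within each side, which lowers the counts of genes. The other divisions are therefore no reference for chance, and nothing is concluded from them for probe sets, genes and chromosomes. For lists, the division that gave 11 called 0 genes. A count of 7 lists at the preset correlation of camera is thus not particular to the real division.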
